A study of Rattus norvegicus with 6 samples.

How the data were processed

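Total RNA from livers of male Wistar rats, for 6 samples, was extracted with a column kit, and biotin-labelled amplified RNA was made with a 3' IVT express kit and hybridised to Affymetrix rat arrays, per the labels' protocols. The authors deposited 1 intensity value per probe set and array, processed with RMA per the submitters' processing notes; the version and the software are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a probe set, so differences in total signal between arrays are largely removed before deposit, and a change shared by most genes would not be visible. RMA normally returns log2 values. The deposited intensities ran from 3.61 to 21668 and were therefore read as linear, and log2 was taken before every test; the design of the tests had assumed values deposited as log2, and nothing else in it was altered.

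Samples were grouped by their titles and source names into control (15P) and low protein (5P), 3 arrays each. Of 31099 probe sets, 57 Affymetrix control probe sets were left out and 31042 were tested without an intensity filter. Gene names come from the platform's annotation, which can be old, checked through gene IDs against the RefSeq table of assembly GRCr8, which changed 0 symbols. Among the tested probe sets 20826 had 1 gene symbol, 436 had several and 9780 were unnamed here; the gene ID of 20758 of the 20826 matched the table, and the file's name was kept for the other 68. Where a gene had several probe sets, the one with the highest mean over the 6 arrays stood for it, which gave 14217 genes. No genome coordinates are given, since the sources name no build.

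Low protein was compared with control by a linear model per probe set and per gene with empirical Bayes moderation (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probe sets or all genes and a threshold of 0.05. The residual degrees of freedom were 4, and 8.38 with those of the prior for probe sets. Log2 fold changes are low protein minus control, so that positive values are higher in low-protein livers, and their SE is the moderated one. Values given as mean ± SD are log2 intensities over the 3 arrays of a diet. Gene lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from each list and with fry, each adjusted over the 27 lists. Of 457 genes in the lists 397 were measured. The lists cover the amino acid response, amino acid degradation, cholesterol and fatty acid synthesis, fatty acid oxidation, growth hormone, FGF21 receptors, glucose, bile acids, the clock, NRF2, endoplasmic reticulum chaperones, acute phase and secreted proteins, cell cycle, ribosomal proteins, hepatocyte zones and markers of 9 other cell types.

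The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Fgf21, then the 12 largest rises and 12 largest falls among genes that passed with groups that did not overlap, filled with the genes of smallest p where fewer passed, and then up to 4 members of smallest p per list. It gave 116 genes, of which the text describes a part. Members of a list outside the rule that are named were chosen after their values were seen: Atf4, Fasn, Scd, Cps1, Arg1, Igf1, Ghr, Igfbp1, Igfbp2 and Cyp7a1. The 5 fallen genes beyond the 12 largest falls, and the genes of the lists in the closing observations, were chosen in the same way.

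The alternatives were an intensity-dependent or robust prior variance, centring of arrays on the median or 75th percentile, quantile normalization, filters at the 25th and 50th percentile of mean intensity, array weights, the replicate number as a block, each array left out in turn, and a gene taken as the mean of its probe sets or as its probe set of largest SD. The procedure was tested on simulated data with the number of probe sets and arrays of this comparison. Each value was drawn independently, with the moderated spread of its probe set or gene. Over 31042 probe sets it recovered 97 of 100 probe sets changed by 1 on the log2 scale and 99 of 100 changed by 2, with 10 false calls, and it made 0 calls when nothing was changed. Over 14217 simulated genes in lists of 20, it recovered 3 of 3 lists shifted by 0.5 with 0 false lists. Since the simulated genes were independent, this does not test camera on lists whose genes move together. The correlation estimated here was 0.528 in the cholesterol list and 0.56 in the cell cycle list. Measured changes of the simulated size did not always pass, such as Vnn1 at 1.49 and Fgf21 at 1.99. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.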

Results

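Liver RNA from male Wistar rats was measured on 6 Affymetrix expression arrays, 3 from rats given a control diet (15P) and 3 from rats given a low-protein diet of the same energy content (5P). Per the labels, the rats weighed about 150 g on arrival. They had 4 days on pellets and were then trained for 4 days to eat the control diet in a daily window. On the sampling cycle each rat ate its assigned diet for 8 hours, and the liver was taken after a further 16 hours without food. The comparison therefore asks how the liver transcriptome differed after a single feeding period on little protein, and the series title names fibroblast growth factor 21, growth and lipid metabolism as its subject. The deposited table held 31099 probe sets with RMA intensities on a linear scale, and the median intensity per array ran from 33.34 to 34.32. After 57 control probe sets were set aside, 31042 were tested, and the 20826 probe sets with 1 gene symbol stood for 14217 genes. Arrays carry no read depth, and each diet was measured on 3 arrays. The labels do not say outright that each array is a separate animal, and the p-values measure only the spread between these samples.

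Low-protein livers carried more RNA for enzymes that make asparagine and serine and less for enzymes of cholesterol synthesis, fatty acid desaturation and ornithine breakdown. Among genes that passed the test, the largest rises were in Asns, Phgdh and Psat1, with log2 fold changes of 3.36, 3.07 and 2.67 (SE 0.365, 0.371 and 0.341), and the largest falls were in Oat, Fads1 and Fads2, at -2.48, -2.20 and -2.02 (SE 0.224, 0.210 and 0.178). Fgf21, the gene of the series title, was higher on all 3 low-protein arrays but did not pass the test. At an adjusted p under 0.05, 26 genes passed, of which 9 rose and 17 fell, and no gene moved by more than 3.36 on the log2 scale. Among probe sets 41 passed, 11 upward and 30 downward; 33 of them had 1 gene symbol, 1 had several, and 7 were unnamed here, all 7 of which fell. All 26 genes had groups that did not overlap, as had 22.9% of all genes, where chance gives 10%. An unadjusted p under 0.05 was reached by 2319 genes, 1185 higher and 1134 lower, against 711 expected by chance.

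Array choice and scaling moved these counts. Without control replicate 3 the counts were 109 probe sets and 54 genes; without control replicate 1 they were 17 and 12, and without control replicate 2 they were 17 and 14. Without low-protein replicates 1, 2 and 3 they were 22, 16 and 18 probe sets and 20, 15 and 17 genes. Control replicate 3 stood apart from the other controls: on the first principal component, which held 36.9% of the variance, it scored -10.11, against -26.91 and -22.45 for control replicates 1 and 2 and 17.34 to 22.59 for the low-protein arrays. Of the 26 genes, 9 passed in each of the 6 fits that left out 1 array (Atf5, Insig1, Akap8l, Cyp51, Fads2, Fdps, Oat, Tm7sf2 and Fads1). The share of passing probe sets that rose was 26.8% as deposited, 16.7% with the arrays centred on their medians and 40.7% with the arrays centred on their 75th percentiles. For genes the shares were 34.6% as deposited, 26.5% with median centring and 47.4% with 75th-percentile centring. None of the 3 rescalings shifted the median fold change of all probe sets by more than 0.049 (log2).

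**Figure D1:**
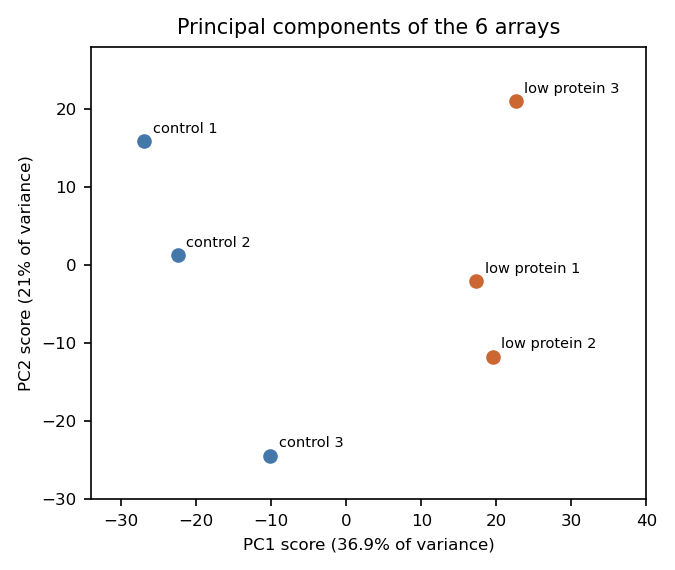
Scores of the 6 arrays on the first (horizontal axis, 36.9% of variance) and second (vertical axis, 21% of variance) principal components of the log2 intensities, with blue points for control and orange for low-protein arrays. The diets separate along the horizontal axis, and control replicate 3 at -10.11 lies closest to the low-protein arrays.

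Genes of the amino acid response, the program that the transcription factor ATF4 drives when amino acids are scarce, were higher in low-protein livers. Of 34 measured members 4 rose, none fell and 30 did not pass; adjusted over the list alone, 12 rose. Asns (gene ID 25612), the enzyme that makes asparagine, went from a log2 intensity of 5.11 ± 0.28 to 8.46 ± 0.83 (SD, n = 3 each), a 10.2-fold rise (adjusted p = 0.0231). Phgdh and Psat1, enzymes of serine synthesis, rose 8.40-fold and 6.38-fold (adjusted p = 0.0354 and 0.0359), and the transcription factor Atf5 rose 3.28-fold, from 9.17 ± 0.19 to 10.88 ± 0.12 (adjusted p = 0.00533). Atf4 itself had a log2 fold change of 0.08 (SE 0.196; -0.09 without low-protein replicate 2 and 0.30 without low-protein replicate 3). The stress protein gene Nupr1 had a log2 fold change of 1.02 (SE 0.154) and did not pass over all genes (adjusted p = 0.0593), though it did without low-protein replicate 1 (1.19, adjusted p = 0.0316, the range over all alternatives being 0.0316 to 0.163). The list as a whole was shifted upward (27 of 34 higher, median log2 fold change 0.30, limma's camera, adjusted p = 7.66e-08), with an adjusted p = 0.37 with an estimated correlation. Its mean was highest on low-protein replicate 2 (0.90 above control replicates 1 and 2), as was that of the red blood cell markers (0.42). Single arrays decided some calls: Asns passed in 3 of the 6 leave-one-out fits (adjusted p = 0.0675, 0.066 and 0.0522 without control replicates 1 and 2 and low-protein replicate 3), Phgdh in 2 (0.102, 0.0561, 0.0571 and 0.0942 without control replicates 1 and 3 and low-protein replicates 2 and 3) and Psat1 in 1 (0.017 without low-protein replicate 3, 0.0596 to 0.112 without any other array). With a robust prior variance these 3 had an adjusted p = 0.0517, 0.0589 and 0.0602.

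Cholesterol synthesis genes were lower throughout. All 20 measured members of the list were lower in low-protein livers, with a median log2 fold change of -0.91; 5 fell and 15 did not pass over all genes, and 18 fell when adjusted over the list alone. Insig1, a sterol-regulated protein of the endoplasmic reticulum, fell from 10.37 ± 0.22 to 8.55 ± 0.14 (SD, n = 3 each), or 3.52-fold (adjusted p = 0.00533). Cyp51 and Fdps, enzymes of sterol and isoprenoid synthesis, fell 3.47-fold and 3.41-fold (adjusted p = 0.00728 for both), and the second Cyp51 probe set gave a log2 fold change of -1.71. Tm7sf2 and Ebp, enzymes of later sterol steps, fell by 1.25 (SE 0.108) and 0.87 (SE 0.115) on the log2 scale. Ebp passed in none of the 6 leave-one-out fits (adjusted p = 0.0522 to 0.131), nor with 75th-percentile centring (0.0512). The shift of the list had an adjusted p = 1.45e-22 by camera and an adjusted p = 0.203 with an estimated correlation.

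Fatty acid and triglyceride synthesis genes were lower in 18 of 22 cases, with a median log2 fold change of -0.49. The desaturase genes Fads1 and Fads2, which act on polyunsaturated fatty acids, fell 4.60-fold and 4.06-fold (adjusted p = 0.00988 and 0.00728). Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, fell 1.94-fold (adjusted p = 0.0362); it passed in 1 leave-one-out fit, without low-protein replicate 2 (0.0475), and not in the others (0.0671 to 0.113) or with 75th-percentile centring (0.0502). No member rose, 19 did not pass, and 10 fell when adjusted over the list alone. Pnpla3, a lipase gene under lipogenic control, had a log2 fold change of -2.24 (SE 0.366, adjusted p = 0.0623; -2.70 and 0.00741 without control replicate 2, 0.00741 to 0.168 over the alternatives), and its other probe sets had -3.11 and -0.97. Among members that did not pass, Fasn, the fatty acid synthase, had -1.77 (SE 0.475), and the stearoyl-CoA desaturase gene Scd had -0.16 (SE 0.237; 0.14 without low-protein replicate 3 and -0.33 without low-protein replicate 2). The list was shifted downward (adjusted p = 2.01e-08 by camera, and an adjusted p = 0.203 with an estimated correlation).

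Urea cycle and amino acid degradation genes were lower as a group, and 1 of 46, Oat, fell. Oat (gene ID 64313), which degrades ornithine in mitochondria, went from 11.54 ± 0.19 to 9.05 ± 0.48 (SD, n = 3 each), a 5.59-fold fall (adjusted p = 0.00728). Adjusted over the list alone, 17 fell and 29 did not pass. Aldh4a1, of proline breakdown, had a log2 fold change of -0.66 (SE 0.096, adjusted p = 0.0593), and the urea cycle enzymes Otc and Ass1 had -0.67 (SE 0.106) and -0.75 (SE 0.134), with Cps1 at -0.23 (SE 0.09) and Arg1 at -0.12 (SE 0.118); the second Cps1 probe set had -0.70. Arg1 stood at 0.006 without low-protein replicate 3. Aldh4a1 passed with an intensity-dependent prior variance (adjusted p = 0.0391), with median centring (0.0419), with the filter at the median intensity (0.0475), with array weights (0.0441) and with averaged probe sets (0.0466), the range over all alternatives being 0.0391 to 0.173. In all, 33 of 46 were lower with a median of -0.20, and the shift had an adjusted p = 6.51e-10 by camera and an adjusted p = 0.203 with an estimated correlation.

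Periportal hepatocyte genes, which mark the liver cells nearest the portal vein, shared 8 of their 11 measured members with the degradation list. All 11 were lower, with a median of -0.28; none passed over all genes, and 5 fell when adjusted over the list alone. The serine dehydratase gene Sds had a log2 fold change of -1.89 (SE 0.432, adjusted p = 0.117; -2.42 and 0.0176 without control replicate 3, 0.0176 to 0.267 over the alternatives), and the histidine pathway gene Uroc1 had -0.56 (SE 0.103). Camera gave an adjusted p = 8.35e-06, with an adjusted p = 0.202 with an estimated correlation. The median was -0.43 without control replicate 2 and -0.44 without low-protein replicate 3. Pericentral genes, of the cells nearest the central vein, were not shifted (adjusted p = 0.871, 0.919 with an estimated correlation). Of their 10 measured members Oat fell, and adjusted over the list alone 2 rose and 1 fell. The retinal dehydrogenase gene Aldh1a1 had a log2 fold change of 1.18 (SE 0.232, adjusted p = 0.0868; 1.49 and 0.00642 without control replicate 3, 0.00642 to 0.221 over the alternatives). The pericentral median was 0.08, the test pointed upward and the mean was -0.15. The test pointed downward with fry, with 75th-percentile centring and without low-protein replicates 1 and 3 (medians 0.08, 0.12, 0.05 and 0.05).

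Fgf21 (gene ID 170580), a hepatic hormone of fasting and amino acid shortage, read 5.17, 5.60 and 6.62 (log2) on the control arrays and 7.38, 8.46 and 7.52 on the low-protein arrays. Its log2 fold change was 1.99 (SE 0.386), or 3.98-fold higher, and it did not pass over all probe sets (adjusted p = 0.0858), nor over genes (0.087). Without control replicate 3 the log2 fold change was 2.40 (adjusted p = 0.042). Over 14 alternative settings the adjusted p ranged from 0.042 to 0.212. In the list of FGF21 and its receptors, 5 measured members gave 1 rise and 1 fall adjusted over the list alone, Fgf21 and the receptor gene Fgfr2 (-0.46, SE 0.101), and none over all genes. Fgfr2 ran from -0.54 to -0.03 over all alternatives, and from -0.54 to -0.41 over the left-out arrays. Another of the 5 Fgfr2 probe sets had 0.25, with an unadjusted p under 0.05. The receptor genes Fgfr4 and Fgfr1 had log2 fold changes of -0.20 (SE 0.097; -0.12 without low-protein replicate 2) and -0.06 (SE 0.086; -0.02 and -0.11 without control replicates 1 and 3), and the second Fgfr1 probe set had 0.30, also with an unadjusted p under 0.05. The list was not shifted (adjusted p = 0.386, 0.539 with an estimated correlation), its median being -0.06, its mean 0.24 and its test downward. That median was -0.03 without control replicate 1, -0.16 without control replicate 3 and -0.12 without low-protein replicate 3.

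Growth hormone and insulin-like growth factor genes had no member past the test among 17, over all genes or adjusted over the list alone. Igf1 had a log2 fold change of -0.17 (SE 0.088), Igfals, the serum carrier of IGF complexes, -0.56 (SE 0.185), the signal transducer Stat5b -0.50 (SE 0.147) and the growth hormone receptor Ghr -0.23 (SE 0.128; -0.10 without low-protein replicate 2). Igfbp2 had 1.05 (SE 0.499; 1.63 and 0.66 without control replicate 3 and low-protein replicate 3). Igfbp1 had 0.50 (SE 0.513), which turned to -0.13 without control replicate 1 and was 1.10 without control replicate 3. The list median was -0.10 (adjusted p = 0.161, 0.513 with an estimated correlation), with an adjusted p = 0.0367 without low-protein replicate 3 (median -0.09, 0.0367 to 0.513 over the alternatives) and a median of -0.15 without control replicate 3.

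**Figure D2:**
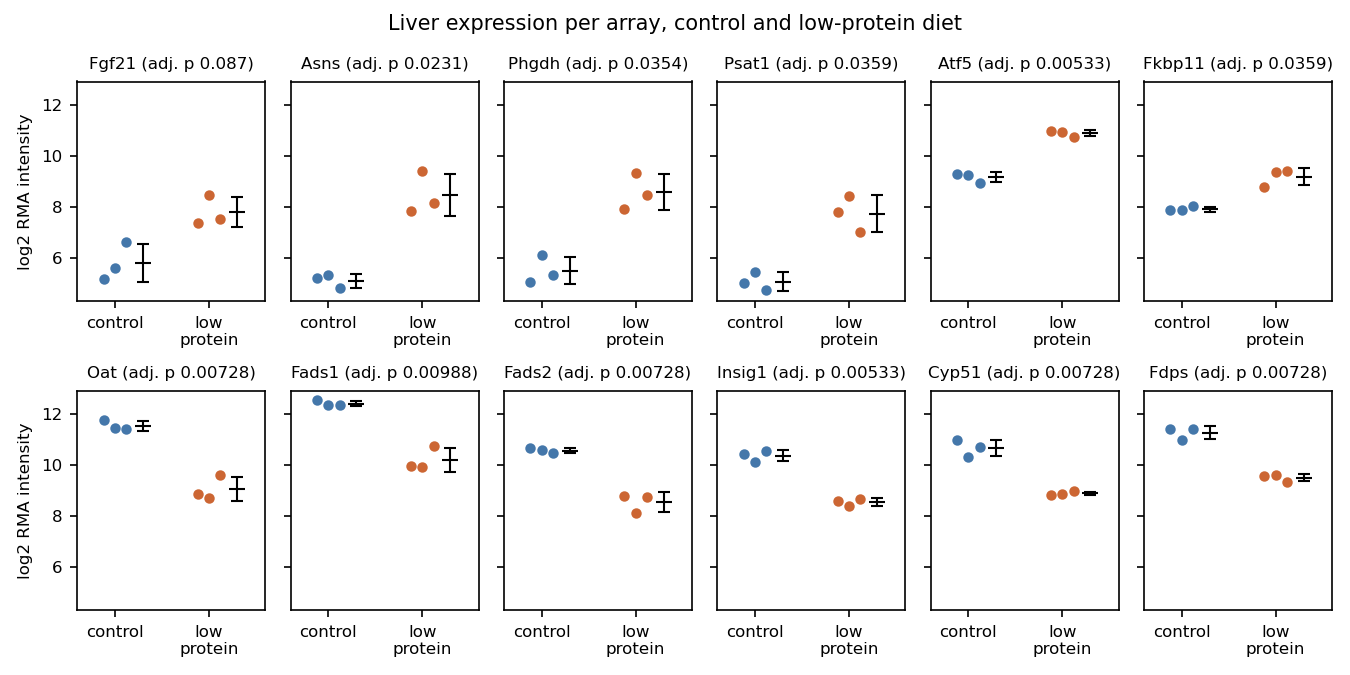
Log2 RMA intensity (vertical axes) of 12 genes on each array, with blue points for the 3 control and orange for the 3 low-protein arrays; the black marks are the mean and SD of each diet, and each title gives the adjusted p over genes. The 3 low-protein points for Fgf21 lie between 7.38 and 8.46, above the control points at 5.17 to 6.62, and those for Oat lie below the control points.

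Fatty acid oxidation, ketogenesis and PPARalpha target genes were higher as a group without any member passing over all genes. Of 22 measured, 16 were higher, the median log2 fold change was 0.36, and 6 rose when adjusted over the list alone. Vnn1, a pantetheinase gene under PPARalpha control, had 1.49 (SE 0.223, adjusted p = 0.0593; 0.0329 and 0.0396 without control replicates 1 and 3, 0.043 with array weights, 0.0329 to 0.138 over the alternatives), the thioesterase gene Acot2 had 0.95 (SE 0.178) and the carnitine carrier gene Slc25a20 had 0.45 (SE 0.09). The shift had an adjusted p = 0.000174 by camera and an adjusted p = 0.394 with an estimated correlation. Red blood cell markers were also higher, with Hbb at 0.48 (SE 0.084), Alas2 at 0.43 (SE 0.098), Slc4a1 at 0.14 (SE 0.114) and Epb42 at -0.06. The oxidation list was highest on another array than the red blood cell list. On low-protein replicates 1, 2 and 3 the oxidation mean stood 0.656, 0.335 and 0.423 above control replicates 1 and 2. The red blood cell mean stood 0.218, 0.417 and 0.206 above them.

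All 19 measured cytosolic ribosomal protein genes were higher, with a median of 0.30; none passed over all genes and 17 rose when adjusted over the list alone. Rpl4 had a log2 fold change of 0.70 (SE 0.132, adjusted p = 0.0848; 0.83 and 0.0417 without control replicate 3, 0.0417 to 0.218 over the alternatives) and Rpl18 had 0.44 (SE 0.11). Endoplasmic reticulum chaperone genes were higher in 16 of 18 cases, with a median of 0.28 and 6 rises adjusted over the list alone, among them the calcium-binding chaperone Calr at 0.62 (SE 0.114) and Dnajb11 at 0.58 (SE 0.104). Creld2, induced by stress of that organelle, had 1.02 (SE 0.237, adjusted p = 0.119; 1.34 and 0.0124 without low-protein replicate 1, 0.0124 to 0.26 over the alternatives). Camera gave the ribosomal list an adjusted p = 9.01e-10 and the chaperone list an adjusted p = 2.56e-05; with an estimated correlation the adjusted p = 0.391 and 0.394. The red blood cell markers Hbb and Alas2, at 0.48 and 0.43, moved in the same direction as both groups, with Slc4a1 at 0.14 and Epb42 at -0.06. On low-protein replicates 1, 2 and 3 the ribosomal mean stood 0.182, 0.338 and 0.4 above control replicates 1 and 2. The chaperone mean stood 0.092, 0.436 and 0.394 above them, and the red blood cell mean 0.218, 0.417 and 0.206. The ribosomal mean was highest on low-protein replicate 3 and the red blood cell mean on replicate 2. On replicates 1 and 3 the red blood cell means were nearly equal (0.218 and 0.206), so the order of the 3 arrays decides nothing.

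NRF2 targets, genes of the antioxidant response, were higher in 15 of 17 cases with a median of 0.26. None passed over all genes and 2 rose when adjusted over the list alone, the glutathione transferase gene Gsta3 at 2.33 (SE 0.437) and the aldehyde reductase gene Akr7a3 at 1.51 (SE 0.37). The quinone reductase gene Nqo1 had 1.71 (SE 0.685), with a low-protein SD of 1.57 against 0.54 in controls; it was 1.02 without low-protein replicate 2 and 2.57 without low-protein replicate 1. The shift had an adjusted p = 0.00114 by camera and an adjusted p = 0.394 with an estimated correlation. The list mean was highest on low-protein replicate 2 (0.84 above that of control replicates 1 and 2), as was that of the red blood cell markers (0.42).

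Cell cycle genes were higher in 20 of 21 cases with a median of 0.26, and none passed over all genes or adjusted over the list alone. The replication factor genes Pcna and Mcm5 had log2 fold changes of 0.53 (SE 0.139) and 0.46 (SE 0.127), from control means of 8.75 and 5.81. Much of the list had low signal: its mean on control replicate 3 was 5.17 (log2), where the median of all probe sets was 5.07. The shift had an adjusted p = 0.00164 by camera and an adjusted p = 0.539 with an estimated correlation, and it was lost without control replicate 3 (median 0.28, adjusted p = 0.0735) and without low-protein replicate 2 (median 0.10, adjusted p = 0.191); without low-protein replicate 3 the median was 0.45 (adjusted p = 1.16e-08). The red blood cell markers Hbb and Alas2 were also higher, at 0.48 (SE 0.084) and 0.43 (SE 0.098), with Slc4a1 at 0.14 and Epb42 at -0.06. The cell cycle and red blood cell lists both had their highest mean on low-protein replicate 2 (0.57 and 0.42 above control replicates 1 and 2).

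Acute phase protein genes were lower in 13 of 16 cases with a median of -0.09, and none passed over all genes or adjusted over the list alone. A2m had -0.61 (SE 0.152) and Crp -0.52 (SE 0.145), and the iron hormone gene Hamp had -1.68 (SE 0.872), which was -0.55 without low-protein replicate 3. Camera gave an adjusted p = 0.00787, against an adjusted p = 0.513 with an estimated correlation and an adjusted p = 0.131 without control replicate 1 (median -0.02); without control replicate 3 the median was -0.14 (adjusted p = 0.00205). Secreted transport protein and apolipoprotein genes were not shifted (18 measured, none passing over all genes or adjusted over the list alone, median 0.008, mean -0.012, the test pointing downward, adjusted p = 0.567, 0.634 with an estimated correlation), with Apoa1 at -0.19 (SE 0.094) and Apoa2 at -0.27 (SE 0.123; -0.15 without low-protein replicate 2).

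Among bile acid genes the canalicular transporter Abcc2 fell 2.65-fold, by 1.41 on the log2 scale (SE 0.171, adjusted p = 0.0354), and the other 15 of 16 did not pass. Adjusted over the list alone, 2 fell, Abcc2 and the uptake carrier gene Slco1a1 (-0.44, SE 0.097). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.05 (SE 0.213; -0.30 and 0.11 without low-protein replicates 1 and 2). Abcc2 passed without control replicate 1 (0.0329) and in no other leave-one-out fit (0.0561 to 0.0948). The list had a median of -0.09 and an adjusted p = 0.0469 by camera, with an adjusted p = 0.394 with an estimated correlation. It lost the call without control replicates 2 and 3 (0.0547 and 0.268), without low-protein replicates 2 and 3 (0.121 and 0.145), and with median centring, the filter at the median intensity and array weights (0.0688, 0.0842 and 0.121), and fry gave an adjusted p = 0.21. It passed in 6 of 16 alternatives. Over all alternatives the adjusted p ranged from 0.00714 to 0.394, and the median was -0.15 without control replicate 1 and -0.06 without control replicate 3.

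Glucose production genes were not shifted (adjusted p = 0.451, 0.715 with an estimated correlation). Of 15 measured none passed over all genes and 3 rose when adjusted over the list alone, the glycogen synthase gene Gys2 at 0.50 (SE 0.102), the pyruvate carboxylase gene Pc at 0.40 (SE 0.083) and the fructose bisphosphatase gene Fbp1 at 0.39 (SE 0.108). The list median of 0.13 was -0.08 without control replicate 1, 0.01 and 0.04 without low-protein replicates 1 and 2, and 0.27 without low-protein replicate 3. Clock genes were not shifted either (17 measured, none passing over all genes or adjusted over the list alone, median -0.05, adjusted p = 0.0894, 0.391 with an estimated correlation). Bhlhe40 had -0.55 (SE 0.154) and Per3 -0.50 (SE 0.146), with 0.19 in the second Per3 probe set. The list had an adjusted p = 0.0166 without control replicate 1 (median -0.09, 0.0166 to 0.391 over the alternatives). Its median was 0.003 and -0.006 without control replicates 2 and 3, and -0.08, -0.08 and 0.006 without low-protein replicates 1, 2 and 3, the test pointing downward in each.

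Among the remaining named genes, 5 rose that belong to none of the lists: Fkbp11, a peptidyl-prolyl isomerase of the secretory pathway, Colq, Tmem120a, Dctpp1 and Timm8a1, by 1.27 (SE 0.163), 1.16 (SE 0.145), 0.94 (SE 0.117), 0.81 (SE 0.101) and 0.72 (SE 0.096) on the log2 scale, each with an adjusted p between 0.0354 and 0.0374. Acadsb, a dehydrogenase of branched-chain acid breakdown, fell by 1.45 (SE 0.191, adjusted p = 0.0374), and Akap8l, a nuclear anchoring protein, fell by 1.02 (SE 0.091, adjusted p = 0.00728). Without single arrays, Fkbp11, Colq, Tmem120a, Timm8a1 and Acadsb passed in 1 of 6 fits each and Dctpp1 in none. The failing fits had an adjusted p of 0.0507 to 0.117 for Fkbp11 (passing without low-protein replicate 1, 0.0124), 0.0522 to 0.109 for Colq, 0.0565 to 0.11 for Tmem120a and 0.0987 to 0.131 for Timm8a1 (passing without control replicate 3, 0.0204, 0.0447 and 0.041). For Acadsb they were 0.0699 to 0.108 (passing without low-protein replicate 3, 0.0199), and for Dctpp1 0.0561 to 0.1. With 75th-percentile centring Acadsb and Timm8a1 both had an adjusted p = 0.0502, quantile normalization gave Acadsb 0.0547, and averaging probe sets gave Timm8a1 0.0554. Fkbp4, a co-chaperone of HSP90, had a log2 fold change of 0.54 (SE 0.082) without passing (adjusted p = 0.0593; 0.0484 after quantile normalization, 0.0484 to 0.173 over the alternatives). The other 5 fallen genes, beyond the 12 largest falls and named after their values were seen, were Gpsm2 (-0.77, SE 0.092), Ccnl2 (-0.75, SE 0.093), Ogt (-0.74, SE 0.086), Mknk2 (-0.68, SE 0.085) and Ppp1r10 (-0.63, SE 0.081). With an array left out, Gpsm2, Ccnl2 and Ogt passed only without control replicate 3 (0.0447, 0.0482 and 0.0447), and Mknk2 (0.0584 to 0.113) and Ppp1r10 (0.0596 to 0.117) in no fit.

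Of the 27 gene lists, camera placed 13 past the threshold, 7 upward and 6 downward. With an estimated correlation 0 lists passed (4 at an unadjusted p under 0.05), and limma's fry, which asks only whether the members of a list move one way, gave 6: amino acid response, amino acid degradation, cholesterol synthesis, fatty acid synthesis, ribosomal proteins and periportal genes.

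**Figure D3:**
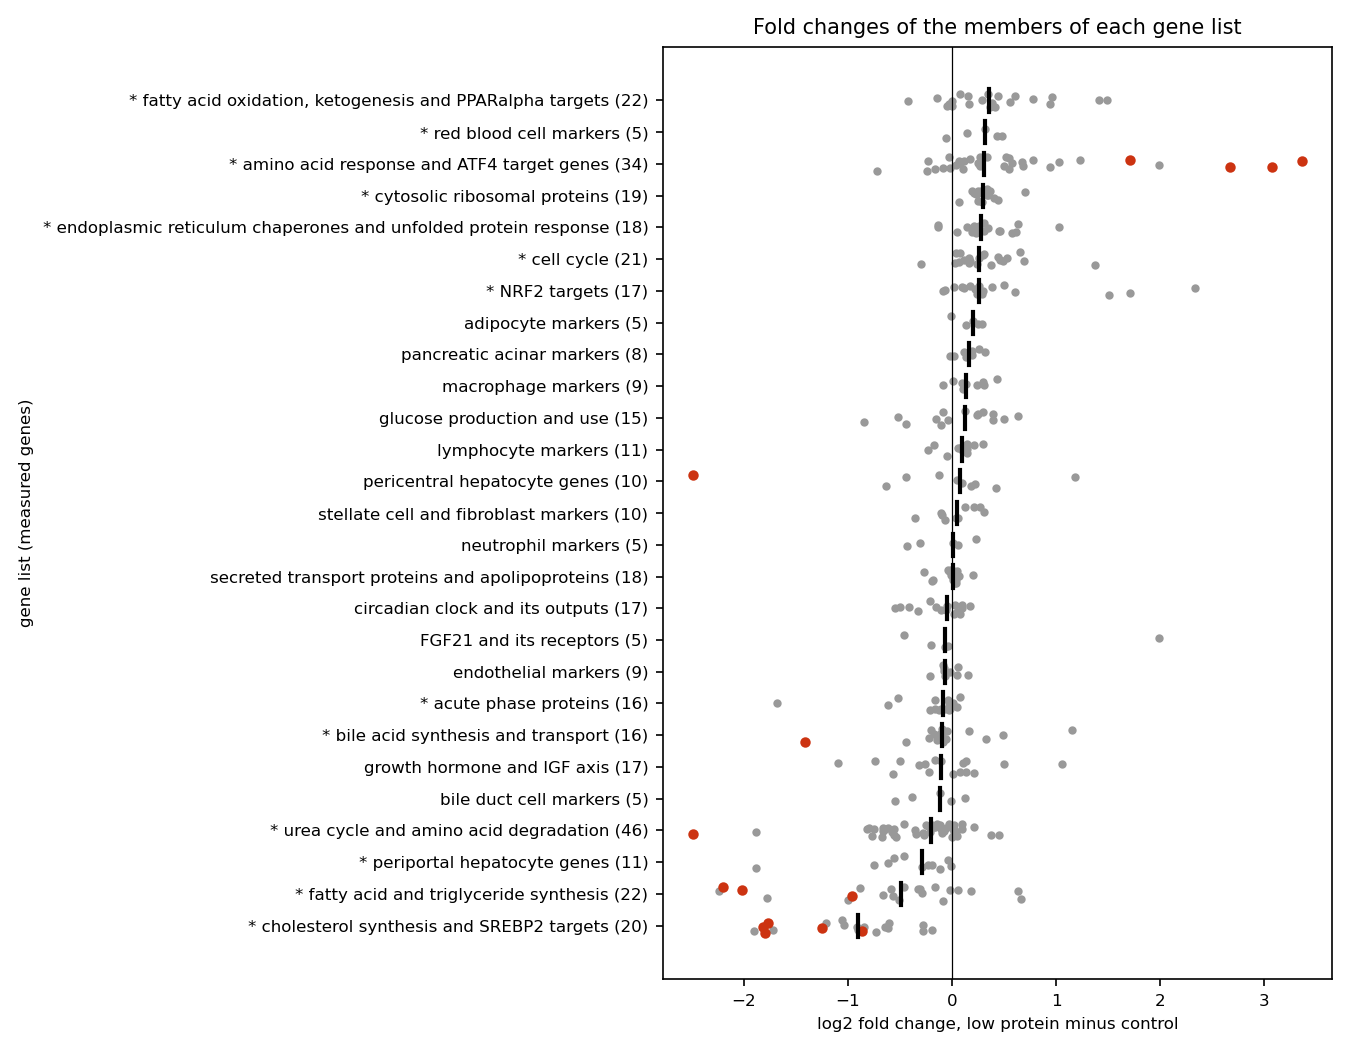
Log2 fold change of low protein over control (horizontal axis) for each measured member of the 27 gene lists (vertical axis, number of measured genes in parentheses); red points passed over all genes, black bars are list medians, and an asterisk marks the 13 lists past the threshold by camera. Medians run from -0.91 for cholesterol synthesis to 0.36 for fatty acid oxidation.

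Markers of other cell types were tested in the same way. Red blood cell markers were shifted upward (5 measured, 4 higher, none passing over all genes, 2 rising when adjusted over the list alone, median 0.32, adjusted p = 0.0207, and an adjusted p = 0.394 with an estimated correlation). The call was lost without low-protein replicate 2 (median 0.19, adjusted p = 0.111, the range over the alternatives being 0.00753 to 0.394). No other marker list was shifted, and none had a member past the test over all genes or adjusted over the list alone. Macrophage markers had a median of 0.14 over 9 genes, with the complement gene C1qa at 0.31 (SE 0.14, 0.20 and 0.19 without control replicate 3 and low-protein replicate 3) (adjusted p = 0.193, 0.634 with an estimated correlation; 0.0372 without control replicate 2, 0.0372 to 0.857 over the alternatives). That median was 0.22 and 0.24 without control replicates 1 and 2, 0.05 without control replicate 3, and 0.21 and 0.04 without low-protein replicates 2 and 3. Bile duct cell markers had -0.11 over 5 genes, with the keratin gene Krt19 at -0.39 (SE 0.133) (adjusted p = 0.195, 0.539 with an estimated correlation; 0.0372 without control replicate 2, 0.0372 to 0.589 over the alternatives), and -0.23 and -0.29 without control replicate 2 and low-protein replicate 3. Lymphocyte markers had a median of 0.10 over 11 genes (adjusted p = 0.451, 0.597 with an estimated correlation; 0.05 without control replicate 2), and stellate cell and fibroblast markers 0.05 over 10 (0.871, 0.919). Endothelial markers had -0.07 over 9 (0.539, 0.857), pancreatic acinar markers 0.16 over 8 (0.225, 0.539) and adipocyte markers 0.20 over 5 (0.195, 0.411). The acinar median was 0.02 without control replicate 2, and the adipocyte median 0.10 without low-protein replicate 2. Neutrophil markers had a median of 0.01, a mean of -0.09 and a test pointing downward over 5 genes (0.871, 0.919).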

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

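All alternatives in this part were chosen before the result was seen. The cause was not tested for any difference below. The number of probe sets past the threshold, 41 as deposited, was 103 with a robust prior variance, 78 with median centring and 102 with array weights; the number of genes, 26, was 43 with array weights. Leaving out 1 array gave 16 to 109 probe sets, 12 to 54 genes and 10 to 14 lists, the highest gene and probe set counts without control replicate 3. Of the 26 genes, 16 passed without control replicate 3 and 10 to 12 passed without any other array. The number of lists, 13, was 0 with an estimated correlation and 6 with fry, and 11 to 13 in the other alternatives with all 6 arrays. The log2 fold change of Fgf21 ran from 1.65 to 2.40 over the leave-one-out fits, passing only at 2.40 without control replicate 3. With the replicate number as a block the counts were 6 probe sets and 14 genes, and the bile acid list had an adjusted p = 0.0799. The numbers do not pair the samples: residuals of same-numbered arrays correlated at -0.087, -0.027 and -0.102, and no array correlated best with its own number. No named gene with an unadjusted p under 0.05 with all arrays turned its direction in 1220 comparisons of gene and setting; 1127 kept direction and side of the threshold, 78 lost the call and 15 gained it. Of 427 comparisons of list and setting 377 kept both, 32 lost the call, 4 gained it and 14 turned the direction of the test, all in lists that were not shifted. These were pericentral genes (median 0.125 with 75th-percentile centring, 0.076 with fry, 0.046 and 0.049 without low-protein replicates 3 and 1, and 0.046 to 0.133 over all left-out arrays), stellate cell markers (0.038 with array weights, -0.011 to 0.006 over 4 left-out arrays and -0.011 to 0.222 over all 6), neutrophil markers (0.046 and 0.065 without control replicate 1 and low-protein replicate 3, -0.157 to 0.096 over all), endothelial markers (-0.025 and 0.052 without control replicate 1 and low-protein replicate 2, -0.135 to 0.052 over all) and FGF21 receptors (-0.015 with averaged probe sets). Filters at the 25th and 50th percentile of intensity left 26 and 32 genes past the threshold, the same 26 among them.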

Other observations

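The gene lists in this part, the splits of probe sets and of genes, the search for a swapped partner of control replicate 3, the fit of a common mixing share to the lists, the shares of the other controls, the difference between lists within an array and the labelling check were chosen after the result was seen. Cytosolic heat shock protein and chaperonin genes were higher in low-protein livers in 22 of 28 cases, with a median log2 fold change of 0.24. None passed over all genes, and 14 rose and 1 fell when adjusted over the list alone. The small heat shock protein gene Hspb1 had 1.09 (SE 0.166), Hspa1a 0.86 (SE 0.201) and the chaperonin subunit gene Cct6a 0.49 (SE 0.085). Red blood cell markers moved in the same direction (median 0.32, with Hbb at 0.48, Alas2 at 0.43, Slc4a1 at 0.14 and Epb42 at -0.06). Over the 8 tests of these lists the adjusted p = 1.26e-07 by camera, with an adjusted p = 0.153 with an estimated correlation. The 21 members not looked at beforehand had a median of 0.21 (adjusted p = 0.00237, and an adjusted p = 0.299 with an estimated correlation). Adjusted over these members alone, 2 rose and 0 fell, while the 14 above include members already seen. Hspb1, Hspa1a and Cct6a had been looked at before the list was made.

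Interferon-induced genes were higher in 20 of 24 cases, with a median of 0.31. None passed over all genes, and 7 rose and 1 fell when adjusted over the list alone. Usp18, which removes the ubiquitin-like modifier ISG15, had 1.25 (SE 0.24) and the antiviral synthetase gene Oas1a had 0.89 (SE 0.165), while the signal transducer Stat2 had -0.36 (SE 0.098). The red blood cell markers Hbb and Alas2, at 0.48 and 0.43, were also higher in low-protein livers, with Slc4a1 at 0.14 and Epb42 at -0.06. Immediate early genes, which respond within minutes to stimuli, were lower in 17 of 21 cases with a median of -0.34. None passed over all genes and 3 fell when adjusted over the list alone; Fos had -2.49 (SE 0.684), Ccn1 -1.48 (SE 0.308) and Egr1 -0.08 (SE 0.437; -0.47 and 0.32 without low-protein replicates 3 and 2). For interferon genes camera gave an adjusted p = 0.000226 and an adjusted p = 0.299 with an estimated correlation, and for immediate early genes an adjusted p = 0.000304 and 0.299. Members not looked at beforehand had medians of 0.23 over 21 interferon genes (adjusted p = 0.00502, 0.357 with an estimated correlation) and -0.26 over 18 immediate early genes (0.00457, 0.299). Adjusted over those members alone, 0 of the 21 interferon genes and 0 of the 18 immediate early genes passed. Usp18, Oas1a, Fos and Ccn1 had been looked at before the lists were made. The immediate early median was -0.16, -0.21 and -0.51 without control replicate 3 and low-protein replicates 2 and 3, and that of its 18 members not looked at beforehand was -0.12, -0.02 and -0.47. The median of the 21 interferon genes not looked at beforehand was 0.13 without low-protein replicate 3.

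RNA processing genes (splicing factors, their kinases and other genes grouped with them) were lower in 48 of 54 cases, with a median of -0.30. Akap8l, Ogt and Ccnl2, all looked at before the list was made, fell over all genes, and 27 fell when adjusted over the list alone. Of the 43 members not looked at beforehand, 0 fell over all genes and 16 fell when adjusted over those 43 alone. Against an intensity-dependent bias, the list median lay -0.231 from the 2.5th percentile of 10000 lists matched on mean intensity, and the 43 members not looked at beforehand had -0.25 against a 2.5th percentile of -0.07. Selection of genes already seen stays open. Those 43 members were lower as a set by camera at its preset correlation (adjusted p = 4.24e-11, 1.06e-11 before adjustment). With their estimated correlation of 0.188, camera gave an adjusted p = 0.153 (0.053 before adjustment). The 43 were measured on the same arrays as the genes already seen and moved together, so their shift cannot decide on selection. Shorter labelled RNA in the low-protein arrays cannot be told apart from the diet. Over 6 control transcripts the 5' minus 3' signal changed by a median of -0.072 (SE 0.053, over transcripts and not arrays), 4 of 6 lower. Both 5' probe sets of the spike-in dap had lower signal (-0.40 and -0.41, adjusted p = 0.0414 over the control probe sets). They read the same transcript, whose middle and 3' probe sets were lower too (-0.283 and -0.175 beside the -0.41). The dap 5' minus 3' signal changed by -0.235 (exact permutation p = 0.4). A diet effect on these genes remains possible and was not tested.

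Control replicate 3 lay between the diets: on an axis from control (0) to low protein (1) built without the array placed on it, it stood at 0.471, and control replicates 1 and 2 at 0.212 and 0.239. A noisier array stays open, since the gap of 0.232 restates that placement and its SD from the mean of the other controls was the highest of the 6 arrays (0.254 against 0.207 to 0.236). A swap needs a low-protein array near the controls, and the lowest of these stood at 0.685. An admixture of low-protein RNA, which needs a single share, cannot be told apart from a rat that responded like the other diet, a biological explanation that was not tested since the labels name no difference between the control rats: in the 54 genes called without control replicate 3, its mean share of the diet difference was 0.409 (SE 0.146, median 0.291) in the 17 that rose and 0.498 (SE 0.074, median 0.55) in the 37 that fell, a difference of -0.089 between the means. The SE of each share, also for the other controls below, is taken over genes of 1 array. Such genes are not independent, and this SE does not measure the spread between arrays. The 13 shifted lists gave a lower share, 0.12 (0 to 0.32, with 0 lists over 2 SD from the mixed value), but control replicates 1 and 2, left out in the same way, had -0.164 (SE 0.082) in 9 fallen genes and 0.348 (SE 0.088) in 12, and 0.212 (SE 0.368) in 3 risen genes and 0.06 (SE 0.025) in 2, so part of such shares may come from the spread between controls; also against admixture, Asns stood at 4.80 (5.20 and 5.32 on control replicates 1 and 2), and 4 of the 13 lists lay on the far side of the other controls.

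Ribosomal protein genes were higher while amino acid degradation genes were lower. An intensity-dependent bias is argued against, since both list medians lay beyond the middle 95% of matched lists, by at least 0.142. A factor per array moves both lists alike, and within an array the mean of the ribosomal list minus that of the degradation list was higher on low protein by 0.64 (SE 0.108, 3 of 3 arrays above all controls), which argues against array scaling as the cause of the opposite movement; the distance of at least 0.451 between the medians under 3 rescalings decides nothing, since 2 of the 3 are centrings, which cannot change it. Shorter labelled RNA was not tested on these lists and stays open, as does a diet effect, which was not tested apart from it. Neither list passed with an estimated correlation (adjusted p = 0.391 and 0.203).

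The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For probe sets 1 of the 10 splits, the real one, gave as many as 41, and the highest of the others gave 1. For genes 1 of 10 gave as many as 26, and the highest other gave 0. For lists 1 of 10 gave as many as 13, and the highest other gave 11.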
